A study of Mus musculus with 4 samples.

How the data were processed

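Dermal cells were sorted by fluorescence from embryonic mice that carry LacZ at Axin2, a feedback gene of Wnt/beta-catenin signalling. Per the labels, ventral foot skin was taken at E17.5 and dorsal back skin at E14.5, and each skin gave 1 Axin2-positive and 1 Axin2-negative library. The 4 libraries fall into 4 groups with 1 library each. Per the labels' protocols, the tissue was digested with hyaluronidase (300 U/ml) and collagenase (1000 U/ml), and cells were sorted from PBS with 4% FBS into Trizol-LS. RNA was purified with a Direct-zol kit, and TruSeq mRNA libraries were sequenced on an Illumina HiSeq instrument. How embryos were pooled, and their litter and sex, are not given in the sources used here.

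The authors processed the reads with TopHat and Cufflinks on mm9, per the labels; versions, settings and the annotation release are not given in the sources used here. The deposited unit is FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per gene or assembled locus, each with a lower and an upper bound and a status, per the file headers. The confidence level of these bounds is not stated in the files. The bounds describe counting and read assignment within a library, not variation between animals. Some deposited FPKM values lie outside their own bounds: among protein-coding genes of at least 5 FPKM this held for 2.30%, 3.48%, 4.52% and 4.37% in the foot positive, foot negative, back positive and back negative libraries, as labelled. Some genes that every cell uses are listed at exactly 0, so a 0 is printed only as "listed at 0", with no fold beside it. Genes listed at 0 still enter the list medians and the counts of genes at least 2-fold apart, unless said otherwise.

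The tables held 43604, 47223, 46924 and 41090 entries in that order, of which 6907, 10608, 10467 and 4644 had no gene name. Entries with the same symbol were summed, and loci that join several genes were kept as 1 unit, which gave 33217 gene units, 831 of them joined. In the table of the foot library labelled positive, 22 symbols altered to calendar dates were restored to their genes. A gene with a status other than OK in any library was left out of counts of higher and lower genes; this removed 544 units. Unnamed loci were not used in the comparisons. Protein-coding status was taken by symbol from a GRCm38 annotation (19696 units), and its coordinates were not used. Gene length was the median over a gene's coding transcripts in GENCODE vM21, also on GRCm38 (18747 coding units had one).

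Read counts were not used here. The relation between FPKM, gene length and the width of the bounds implied about 2.70 M, 6.60 M, 19.2 M and 16.9 M fragments, and the median half-width of the bounds was 23.0%, 14.1%, 8.98% and 9.90% of the FPKM. The foot values are therefore the less precise ones. The lengths come from GRCm38 while the files use mm9, so the implied fragments, and the set of well-measured genes that depends on them, are approximate.

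For each gene the value compared was log2((FPKM + 1)/(FPKM + 1)), which understates changes of low genes. A gene counted as higher or lower when this value was at least 1 in size and the larger FPKM was at least 5. Pairs compared were the labelled positive against negative library in each skin, foot against back for each label, and the foot minus back difference of the log2 ratios. With 1 library per group no test across replicates exists, so there are no p-values and no standard errors. A half-width printed after a log2 ratio combines the authors' bounds of both values in quadrature. It was taken relative to the FPKM without the added 1, so it is too wide for ratios of low genes.

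The median over 4972 genes shifted by -0.26 (foot), 0.18 (back), 0.30 (foot against back, labelled positive) and 0.75 (foot against back, labelled negative) on the log2 scale. Log2 ratios of genes and lists are therefore given after division by median-ratio factors of 1.10, 1.32, 0.891 and 0.785, unless said to be as deposited. FPKM values are printed as deposited.

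Before the data were examined, 41 gene lists were fixed (signalling pathways, skin mesenchyme, patterning, matrix, cell cycle, translation, cell type markers, stress, hypoxia, sex-linked and mitochondrial genes). A list's median over members of at least 1 FPKM in any library was placed among 10000 random lists of equal size matched on expression decile, with seed 11; a list counts as outside when it lies beyond the central 95%. In all, 36 lists had at least 5 members, which made 180 positions. Percentiles describe these libraries only. Genes were named by a rule of the same date: Axin2 in every library, the 8 highest and 8 lowest ratios per comparison whose bounds do not overlap, up to 4 most changed and 2 highest members per list, and any list member at least 2-fold apart with at least 5 FPKM.

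Several choices were made after values were seen. The 8 highest and lowest genes were mostly listed at 0 in a library or had unstable bounds: of 16 genes per comparison, 1, 0, 2 and 4 were well-measured in the foot, the back and the 2 site comparisons. A set of well-measured genes was therefore added (protein-coding, 1 entry and 1 symbol, no 0, FPKM within 10% of its bounds, bounds not wider than the depth implies by over 4 times in fragments). The limits on bounds applied only to values of at least 1 FPKM and were set by each library's own depth. The 8 highest and lowest of these genes per comparison were also named. The genes from which random lists were drawn, and the membership rule, were revised after a first set of list positions had been seen. The bound that would exclude an exchange of the foot labels was tightened after its value was seen. The test on the share of fibroblasts was redefined after marker values had been seen, and its foot outcome was then changed from fitting to undecided by a limit on the spread of the markers. The rule by which a list position counts as reversed (it crosses the middle of the random lists) was widened after values were seen.

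Counts were repeated with pseudocounts of 0.1 and 5, FPKM minimums of 1 and 20 and no minimum, thresholds of 1.5-fold and 4-fold, and scaling by median ratio, by a trimmed mean (30% of log ratios and 5% of expression trimmed) or by quantile normalization. They were also repeated with genes whose bounds do not overlap, without marker genes of other cell types, and with symbols of 1 entry. With FPKM as deposited, lists were also placed by the mean over members, with members of at least 5 FPKM and with a pseudocount of 0.1. Set beside a rescaled position, such a placement therefore differs in scaling as well. These settings were fixed before the data were examined. Added after the data were seen were protein-coding genes only, genes not listed at 0, and well-measured genes.

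The computations were tested on simulated data of 9950 genes per comparison, made from the libraries' own values and depths. Genes changed 2-fold were counted in 37.3% (foot), 22.4% (back), 34.3% (foot against back, labelled positive) and 29.9% (foot against back, labelled negative) of cases. For 4-fold changes the shares were 94.0%, 100%, 98.5% and 100%, and for 8-fold changes 97.0%, 97.0%, 100% and 97.0%, in the same order. Of unchanged genes, 0.378%, 0%, 0.241% and 0% were counted. Among 200 simulated lists of 12 genes without a shift, 4.5%, 3%, 7.5% and 5.5% lay outside; all lists shifted by 0.5 lay above. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.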

Results

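Messenger RNA was measured in dermal cells sorted by an Axin2-LacZ reporter from 2 embryonic skins that make different appendages. Ventral foot skin, taken at E17.5, forms sweat glands, and dorsal back skin, taken at E14.5, forms hair. Each skin gave 1 library labelled Axin2-positive and 1 labelled Axin2-negative, so the 4 groups hold 1 library each and no difference has a replicate check. The authors' bounds implied about 2.70 M and 6.60 M fragments for the foot libraries labelled positive and negative, and 19.2 M and 16.9 M for the back libraries. Site and stage changed together in every foot against back comparison and cannot be told apart. The bounds printed beside values cover counting and read assignment only.

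Axin2, the reporter's own gene and a feedback target of canonical Wnt signalling, was measured in all 4 libraries. In the foot it stood at 9.65 FPKM (bounds 7.10 to 12.5) in the library labelled positive and 12.9 FPKM (10.2 to 15.3) in the library labelled negative. The rescaled log2 ratio was -0.14 ± 0.49, so Axin2 transcript went against the foot label as deposited and did not differ beyond the bounds. In the back it stood at 4.49 FPKM (3.89 to 5.09) in the library labelled positive and 3.13 FPKM (2.63 to 3.64) in the library labelled negative, a log2 ratio of 0.28 ± 0.30. Directions between the sorted fractions below follow the labels, which Axin2 transcript does not bear out in the foot. In the back Axin2 went with the label, and its bounds as deposited did not overlap. The rescaled ratio of 0.28 was below its half-width of 0.30, but this half-width is too wide for low genes. It therefore cannot decide whether the rescaled ratio in the back passed counting error.

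The foot comparison addresses which mesenchymal genes accompany the Axin2 reporter where sweat glands form. Lef1, a nuclear partner of beta-catenin, was higher in the foot library labelled positive, at 8.25 FPKM (6.33 to 10.2) against 3.48 (2.71 to 4.25), a log2 ratio of 1.22 ± 0.47. The receptor gene Tnfrsf19 and the secreted Wnt modulator Dkk2 were also higher there, with log2 ratios of 1.28 ± 0.62 and 0.87 ± 0.35. Fst, which encodes the activin and BMP antagonist follistatin, reached 69.8 FPKM (63.9 to 75.6) against 41.3 (36.7 to 42.6), a log2 ratio of 1.0 ± 0.16. Wnt5a went the other way, at 16.7 FPKM (14.3 to 20.5) against 43.1 (40.6 to 46.2), a log2 ratio of -1.05 ± 0.28. Among 17 Wnt target genes 12 were higher and 5 lower after rescaling, with a median of 0.36 at percentile 96.5, inside the central 95% of random lists.

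Other secreted signals split in the foot. Igf2 had a log2 ratio of 1.42 ± 0.11, Fgf18 of 1.3 ± 0.72 and Fgf7 of 0.93 ± 0.33, all higher in the library labelled positive. Gdf10 was lower there (log2 ratio -2.09 ± 0.56), as were Crabp2 (log2 ratio -1.10 ± 0.29) and the chemokine gene Cxcl12 (-0.90 ± 0.18). Of 14 BMP antagonist genes 11 were higher, with a median of 0.45 at percentile 97.2. Of 11 secreted Wnt inhibitor genes 8 were higher, with a median of 0.42 at percentile 95.5. Neither list passed the central 95%, but BMP antagonists did with a pseudocount of 0.1 (percentile 98.4).

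**Figure D1:**
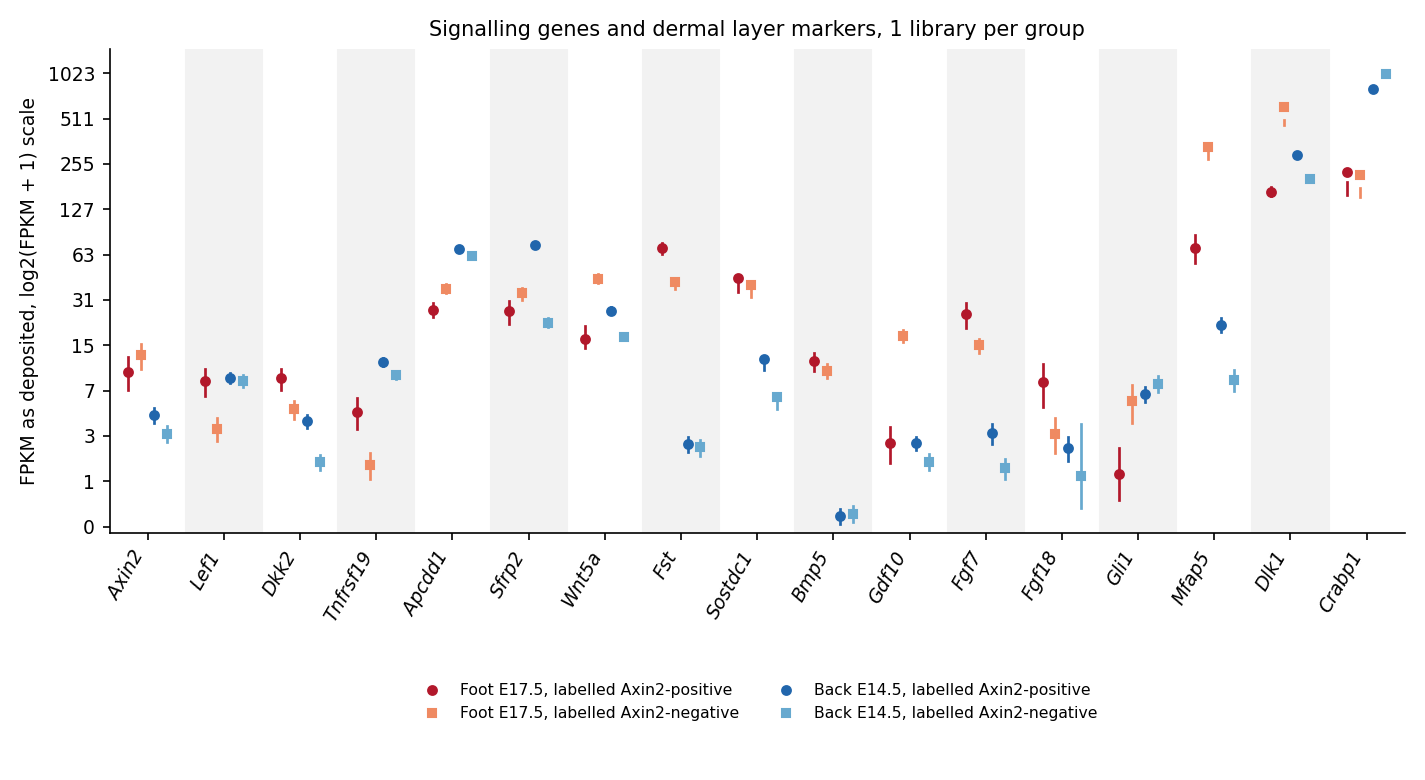
FPKM as deposited of 17 signalling and dermal genes in the 4 libraries on a log2(FPKM + 1) axis; lines are the authors' bounds, and some values lie outside them. Fst stands at 69.8 and 41.3 FPKM in the foot libraries and at 2.53 and 2.36 in the back libraries.

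Genes typical of deep dermis and fascia were lower in the foot library labelled positive. Of 10 lower dermal fibroblast genes 9 were lower, with a median log2 ratio of -1.18 at percentile 0. Mfap5, which encodes a microfibril component, stood at 69.9 FPKM (55.0 to 84.9) against 331 (277 to 312, a value above its own bounds), a log2 ratio of -1.97 ± 0.32. Mest was lower as well, at 277 FPKM (269 to 296) against 583 (578 to 604). The elastic fibre genes Fbn1 and Eln followed, with log2 ratios of -2.45 ± 0.19 and -1.76 ± 0.13. Matrix genes as a group did not move together: 15 of 25 were higher and 10 lower, with a median of 0.08 that is negative as deposited (-0.15). Fn1 was higher at 199 FPKM (175 to 200) against 23.9 (22.8 to 24.9), a log2 ratio of 3.25 ± 0.11. The paired collagen chains went apart, with Col1a2 at 2338 FPKM against 716 and Col1a1 at 262 against 713. Whether this split lies in the cells or in unstable FPKM estimates was not tested.

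Cell cycle genes were higher in the foot library labelled positive, in 22 of 27 members, with a median log2 ratio of 0.49 at percentile 99.99. Kif20a had a log2 ratio of 1.98 ± 0.26, Mki67 of 0.88 ± 0.24 and Birc5 of 0.64 ± 0.22. Mast cell and skeletal muscle markers were higher in the library labelled negative. All 6 mast cell markers were higher in it, with a median of -3.19 at percentile 0, including Tpsb2 at 66.2 FPKM (60.3 to 72.0) against 0.701 (0 to 2.22). Cma1 was further apart, at 165 FPKM (119 to 139, a value above its own bounds) against 1.18. Of 6 skeletal muscle markers 5 were lower in the library labelled positive, with a median of -1.24 at percentile 0.12. Leukocyte markers did not leave the central 95% in the foot, with a median of -0.12 at percentile 39.8. Dissociation stress genes were lower in 11 of 15, with a median of -0.43 at percentile 1.61, including Fos with a log2 ratio of -1.85 ± 0.47.

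As deposited, 688 genes were at least 2-fold higher and 1262 lower in the foot library labelled positive, of 8210 tested. Leaving out genes listed at 0 gave 567 and 1096 of 7923. After rescaling the split was 841 higher and 753 lower. Among 4465 well-measured genes it was 392 and 358. Chd2 (log2 ratio 3.53 ± 0.88), Fn1 and Prkcdbp (3.04 ± 0.38) were among the highest well-measured genes, and Fuca2 (-3.64 ± 1.36), Lamb2 (-2.99 ± 0.64) and Canx (-2.91 ± 0.40) among the lowest.

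The back comparison asks the same of skin that forms hair. Secreted Wnt inhibitors were higher in the back library labelled positive, in 9 of 11 members, with a median log2 ratio of 0.69 at percentile 100. Sfrp2, a secreted frizzled-related protein gene, stood at 73.5 FPKM (71.2 to 76.8) against 21.6, a log2 ratio of 1.55 ± 0.12. Dkk2, Sfrp1 and Wif1 had log2 ratios of 0.81 ± 0.30, 0.75 ± 0.15 and 0.70 ± 0.13. Wnt2 was higher too, at 4.44 FPKM (3.85 to 5.03) against 1.37 (1.03 to 1.70). Wnt target genes had a median of -0.01 at percentile 28.8 with 8 of 17 higher after rescaling, and of 0.17 at percentile 41.7 with 13 of 17 higher as deposited. Lef1 and Apcdd1 differed by -0.11 ± 0.19 and -0.02 ± 0.07.

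Fibroblast and matrix genes were higher in the back library labelled positive. Of 25 matrix genes 19 were higher, with a median of 0.54 at percentile 100, including Fbn1 (log2 ratio 1.24 ± 0.10), Fbln2 (1.20 ± 0.20) and Lox (1.18 ± 0.09). Of 12 pan-fibroblast genes 9 were higher, with a median of 0.50 at percentile 99.99. Pdgfra, a receptor gene of dermal fibroblasts, stood at 40.2 FPKM (38.1 to 42.5) against 14.2 (13.5 to 15). Lower dermal genes were higher in 7 of 10, with a median of 0.34 at percentile 98.8, including Mfap5 (1.06 ± 0.30) and Cd34 (0.78 ± 0.14). By the mean over members, with FPKM as deposited, lower dermal genes lay inside the central 95%, at percentile 90.9. Other growth factors were higher in 16 of 22, with a median of 0.31 at percentile 99.8, including Igf1 (0.95 ± 0.22). This list lay inside by the mean over members (percentile 94.6) and with members of at least 5 FPKM (percentile 93.4). The axon guidance gene Sema3c had a log2 ratio of 1.77 ± 0.25.

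Blood cell and stress genes were lower in the back library labelled positive. All 8 leukocyte markers and all 6 mast cell markers were lower, with medians of -1.50 and -1.60, both at percentile 0. Cpa3 had a log2 ratio of -1.90 ± 0.16, and Fcer1g stood at 0.803 FPKM (0.327 to 1.3) against 6.52 (5.16 to 7.96). Only 2 erythroid markers could be measured, both lower, with a median of -2.54. Stress genes were lower in 12 of 15, with a median of -1.0 at percentile 0, including Fos at 32.0 FPKM (30.2 to 34.2) against 99.3 (96.4 to 104). Ribosomal protein genes were lower in 28 of 30, with a small median of -0.23 at percentile 0.01. Actb, often used as a reference gene, stood at 202 FPKM (198 to 210) against 1062 (1057 to 1094), a log2 ratio of -2.57 ± 0.05. Marcks had a log2 ratio of -2.62 ± 0.10.

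As deposited, 415 genes were at least 2-fold higher and 211 lower in the back library labelled positive, of 6911 tested. Leaving out genes listed at 0 gave 339 and 141 of 6765. The split was 337 and 283 after rescaling, and 146 and 98 among 4598 well-measured genes. Hmga2 (log2 ratio 2.5 ± 0.36), Btg1 (2.02 ± 0.20), Akap12 (2.02 ± 0.14) and Aspn (1.94 ± 0.20) were among the highest well-measured genes.

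Few genes followed the reporter label in both skins. Of 6305 genes tested in both, 45 were higher in both libraries labelled positive and 32 lower in both, where independent lists would share 16.7 and 17.8. Another 11 were higher in the foot and lower in the back, and 59 the reverse, where 7.18 and 41.4 would be. After rescaling 46 were higher and 35 lower in both, where 17.8 and 15.1 would be shared, and the opposite moves numbered 25 and 28, where 13.8 and 19.3 would be. Across genes the log2 ratios had Pearson r 0.075 and Spearman rho 0.032; genes are not replicates. Among 3548 well-measured genes 13 were higher and 9 lower in both (7.16 and 3.82 for independent lists), and 5 and 11 moved oppositely (3.61 and 7.58). Kera, which encodes the matrix proteoglycan keratocan, had log2 ratios of 1.24 ± 0.41 in the foot and 1.11 ± 0.30 in the back. Fos and Tpsb2 were lower in both. Apod (1.45 and 1.43) and Cdkn1c (-1.33 and -1.3) also moved alike, and were chosen after their values were seen.

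The difference between the ratios asks whether the reporter label marks different programmes in foot and back. Every value of it takes the sign of the foot ratio from the labels. With the foot labels turned round, lower dermal genes, at -1.18 in the foot and 0.34 in the back, would move the same way in both skins. Mast cell markers and stress genes, lower in both libraries labelled positive, would then move in opposite ways. As deposited, 749 genes had a foot ratio at least 2-fold above the back ratio and 2098 at least 2-fold below, of 8816. Without genes listed at 0 these were 534 and 1809 of 8199. After rescaling the counts were 1121 and 1190, and among 4799 well-measured genes 464 and 534. Lower dermal genes had a median difference of -1.01 at percentile 0.04, with 8 of 10 members below 0. Matrix genes had -0.40 at percentile 0.615, pan-fibroblast genes -0.43 at percentile 2.33. BMP and GDF ligands had -0.76 at percentile 1.31, with 4 members above 0 and 6 below, but lay at percentile 78.2 by the mean over members and at 33.4 with members of at least 5 FPKM. Matrix genes also lay inside by the mean, at percentile 2.80. Fbn1 had a difference of -3.69 ± 0.21. Cell cycle genes lay above, with a median of 0.53 at percentile 99.97 and 22 of 27 members above 0. Mast cell markers lay at -1.79 (percentile 0.01), skeletal muscle markers at -1.25 (percentile 0.3) and leukocyte markers at 1.42 (percentile 99.93, or 96.5 with a pseudocount of 0.1). Ribosomal protein genes lay at 0.22 (percentile 97.97), a median that is -0.22 as deposited, and lay inside by the mean over members (percentile 76.5).

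The foot against back comparisons ask how the mesenchyme of the 2 skins differs, for each label in turn, and site, stage and any difference in litters or in the sex of the embryos act together. Implied depth differed as well. Coding genes listed at 0 numbered 8516 and 7659 in the foot libraries labelled positive and negative, and 6074 and 5769 in the back libraries. Fst was higher in the foot by a log2 ratio of 4.07 ± 0.25 between the libraries labelled positive and 3.01 ± 0.26 between those labelled negative. Bmp5 stood at 11.5 FPKM (9.87 to 13.2) and 9.85 (8.65 to 11) in the foot libraries labelled positive and negative, and at 0.168 (0.0380 to 0.313) and 0.214 (0.0793 to 0.363) in the back. Fgf7, a keratinocyte growth factor gene, had log2 ratios of 2.37 ± 0.40 and 2.11 ± 0.40 for the positive and the negative label. Tgfb2 (1.93 ± 0.27 and 2.41 ± 0.32) and Tgfb3 (2.66 ± 0.34 and 2.72 ± 0.32) were also higher in the foot under both labels.

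BMP antagonists were higher in the foot as a group, in 11 of 14 members for the positive label (median 0.81, percentile 99.8) and 12 of 14 for the negative label (0.46, percentile 97.9). Twsg1, Nbl1 and Sostdc1 had log2 ratios of 1.0 ± 0.18, 1.21 ± 0.20 and 1.5 ± 0.22 for the positive label. BMP and GDF ligands were higher for the negative label in 8 of 10 (median 0.98, percentile 99.9, though 79.4 by the mean over members), but not outside for the positive label (0.16, percentile 75.7). BMP target genes were higher for the positive label in 7 of 9 (0.81, percentile 99.2), including Id4 at 2.18 ± 0.50, though inside by the mean (percentile 97.4), and lay at 0.42 (percentile 92.3) for the negative label.

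Axin2 was higher in the foot, with log2 ratios of 0.70 ± 0.44 and 1.11 ± 0.37 for the positive and the negative label. Wnt targets as a list were lower in the foot for the negative label, in 13 of 17 (median -0.98, percentile 0.01). For the positive label 12 of 17 were lower (-0.54), inside the central 95% after rescaling (percentile 2.91) and outside as deposited (percentile 1.33). Apcdd1 had log2 ratios of -1.64 ± 0.17 and -1.46 ± 0.12, Tnfrsf19 of -1.37 ± 0.42 and -2.53 ± 0.48, and Lef1 of -0.33 ± 0.36 and -1.67 ± 0.35. Secreted inhibitors divided by gene. Dkk3 (2.35 ± 0.31 and 2.39 ± 0.35) and Sfrp4 (2.31 ± 0.52 and 2.53 ± 0.82) were higher in the foot, and Sfrp1 (-2.90 ± 0.52 and -1.41 ± 0.27) and Sfrp5 (-1.97 ± 0.60 and -1.82 ± 0.54) lower. The R-spondin genes split as well, with Rspo1 at 11.3 FPKM in each back library and 1.38 and 0.956 in the foot, and Rspo2 at 4.86 and 5.13 FPKM in the foot, 0.0372 in the back library labelled positive and listed at 0 in the other.

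Patterning genes separated foot from back under both labels. Hoxa13 stood at 21.8 FPKM (17.9 to 26.1) and 21.4 (19.0 to 23.9) in the foot, and Hoxd13 at 41.3 (35.0 to 44.3) and 33.0 (28.6 to 35.0), and both genes were listed at 0 in the back libraries. Limb-end Hox genes had medians of 1.57 (percentile 99.95) and 1.80 (percentile 100), with 6 of 7 members higher in the foot for each label. Trunk Hox genes had medians of -2.31 and -2.51, both at percentile 0. Hoxc8 stood at 7.70 FPKM (6.92 to 8.49) and 6.86 (6.16 to 7.57) in the back and was listed at 0 in the foot. Tbx18 (3.21 ± 0.18 and 2.24 ± 0.15), Hand2 (2.65 ± 0.60 and 2.15 ± 0.58), Tbx5 (2.92 ± 1.06 and 2.77 ± 1.28) and Prrx2 (1.39 ± 0.25 and 1.39 ± 0.20) were higher in the foot. Limb and dorsoventral factors as a list had medians of -0.15 and -0.07 (0.11 and 0.60 as deposited), inside the random range, but lay above it with members of at least 5 FPKM (percentiles 99.4 and 99.96).

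**Figure D2:**
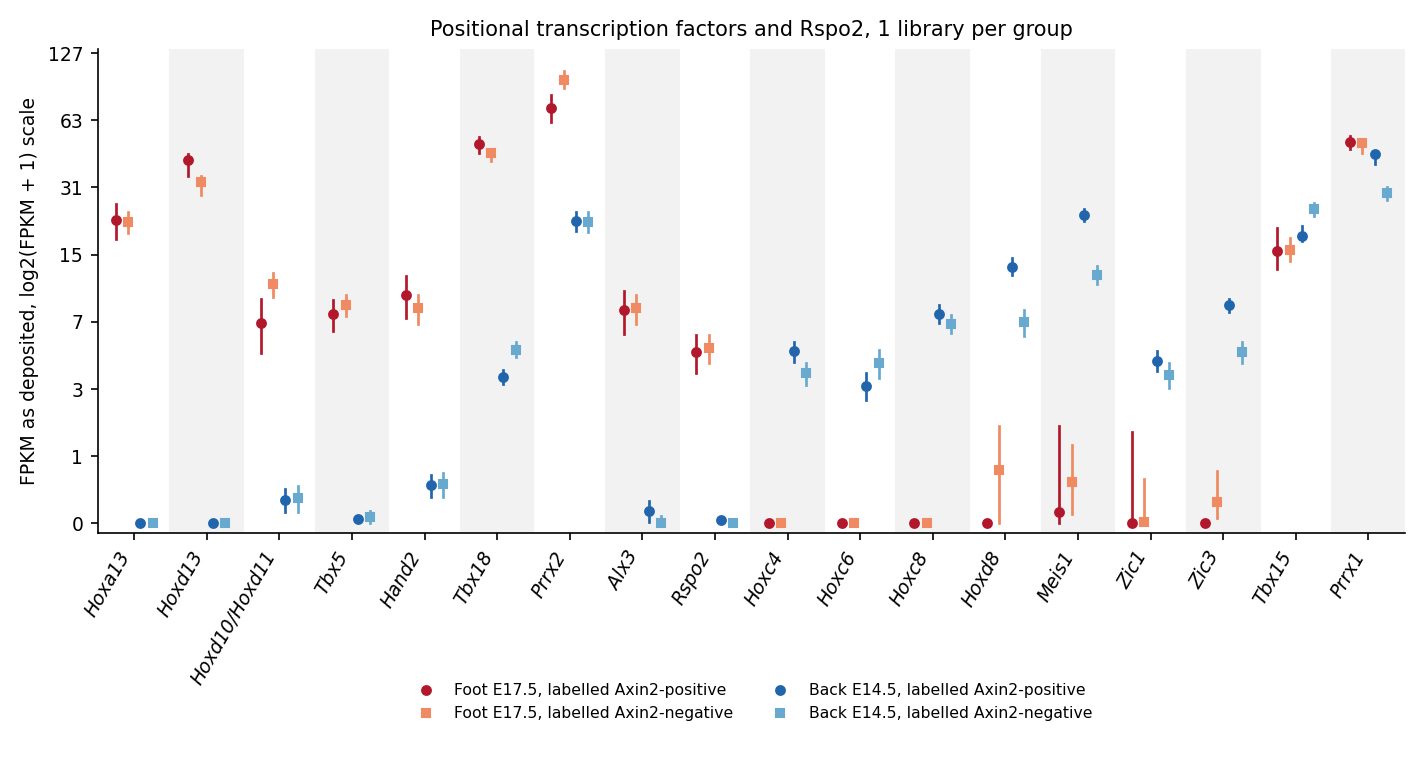
FPKM as deposited of Hox and other patterning genes in the 4 libraries on a log2(FPKM + 1) axis; lines are the authors' bounds. Hoxd13 stands at 41.3 and 33.0 FPKM in the foot libraries and is listed at 0 in both back libraries, while Hoxc8 shows the reverse.

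Matrix genes were higher in the foot after rescaling, in 16 of 25 for the positive label (median 0.55, percentile 99.8, but 95.6 by the mean over members) and 15 of 25 for the negative label (0.99, percentile 100). Postn, which encodes the matricellular protein periostin, stood at 784 FPKM (763 to 820) and 687 (677 to 713) in the foot and at 94.6 (91.5 to 99.1) and 45.6 (42.9 to 48.4) in the back. Fbln2 and Fbln5 had log2 ratios of 2.29 ± 0.13 and 2.10 ± 0.12 for the positive label. Basement membrane genes were lower for the positive label in 10 of 16 (-0.81, percentile 0.46, but 3.20 by the mean), including Egfl6 (-2.57 ± 0.26) and Lamc1 (-1.28 ± 0.51), and lay at -0.17 (percentile 35.2) for the negative label, a median of 0.31 as deposited. Upper dermal genes were lower for the negative label in 8 of 12 (-1.31, percentile 0.01), and at -0.41 (percentile 10.3) for the positive label. Lrig1 had log2 ratios of -1.38 ± 0.52 and -1.43 ± 0.24. Lower dermal genes were higher for the negative label (0.66, percentile 98.3, but 92.5 with quantile normalization). For the positive label they lay at -0.60, inside the central 95% after rescaling (percentile 2.70) and outside as deposited (2.01). Condensate and papilla genes had medians of 0.44 (percentile 98.2) and 0.32 (percentile 95.7), or percentiles 97.1 and 97.7 as deposited and 88.7 and 87.1 with members of at least 5 FPKM. Alpl (1.98 ± 1.01 and 3.52 ± 1.95) and Prdm1 (1.76 ± 0.58 and 1.76 ± 0.46) were higher in the foot.

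Cell cycle genes were lower in the older foot skin, in 24 of 27 for the positive label (median -0.64, percentile 0.07) and 27 of 27 for the negative label (-1.09, percentile 0). Plk1 had log2 ratios of -1.77 ± 0.50 and -2.59 ± 0.46. Axon guidance ligands (-0.74, percentile 2.38) and hypoxia and glycolysis genes (-0.81, percentile 0.52) were lower in the foot for the positive label, including Efna5 (-1.93 ± 0.23) and Ldha (-1.55 ± 0.15). Both lists lay inside the central 95% by the mean over members (percentiles 5.29 and 21.3), and axon guidance ligands also with members of at least 5 FPKM (percentile 2.63).

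Markers of other cells and of handling also differed between the skins. Stress genes were lower in the foot in 15 of 15 for the positive label (median -2.34) and 14 of 15 for the negative label (-2.69), both at percentile 0. Klf6 stood at 12.3 FPKM (10.6 to 14) and 10.9 (9.57 to 11.9) in the foot and at 79.0 (76.4 to 82.9) and 64.0 (62.6 to 66.5) in the back. All 5 keratinocyte markers were lower in the foot, with medians of -2.15 (percentile 0.02) and -2.13 (percentile 0.01). Leukocyte markers were lower for both labels, with medians of -0.82 (percentile 2.09) and -1.88 (percentile 0), and mast cell markers for the positive label (-1.03, percentile 1.13). Only 3 endothelial markers could be measured, with medians of -1.34 and -1.52. Xist stood at 9.26 and 6.36 FPKM in the foot and at 0.00172 and 0.00200 in the back, while the Y-linked gene Ddx3y stood at 9.43, 8.59, 6.86 and 4.98 FPKM in the same order of libraries. Sex was therefore not separated from site and stage.

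As deposited, 1707 genes were higher and 918 lower in the foot for the positive label (of 8004), and 3000 higher and 422 lower for the negative label (of 7963). Leaving out genes listed at 0 gave 1569 and 748 (of 7696) for the positive label, and 2874 and 315 (of 7730) for the negative label. After rescaling the splits were 1115 and 1332, and 975 and 1209. Among well-measured genes they were 549 and 746 of 4747, and 540 and 705 of 4728. Of 7151 genes tested under both labels, 939 were higher and 207 lower in the foot in both, where independent lists would share 464 and 36.3; the 2 ratios share no library. After rescaling 364 and 524 were shared, where 81.4 and 167 would be. Across genes the ratios had Pearson r 0.547 and Spearman rho 0.560; genes are not replicates. Coch (5.44 ± 2.22 and 5.82 ± 0.76) and Lhx2 (3.94 ± 2.02 and 4.38 ± 3.86) were among the highest well-measured genes under both labels, and Tagap (-6.81 ± 0.58 and -6.37 ± 0.31), Rsph3a (-5.56 ± 0.48 and -6.71 ± 0.40) and Klf2 (-4.27 ± 0.89 and -4.14 ± 0.54) among the lowest. Tagap and Rsph3a lie close together on chromosome 17, and whether they are separate changes was not tested.

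**Figure D3:**
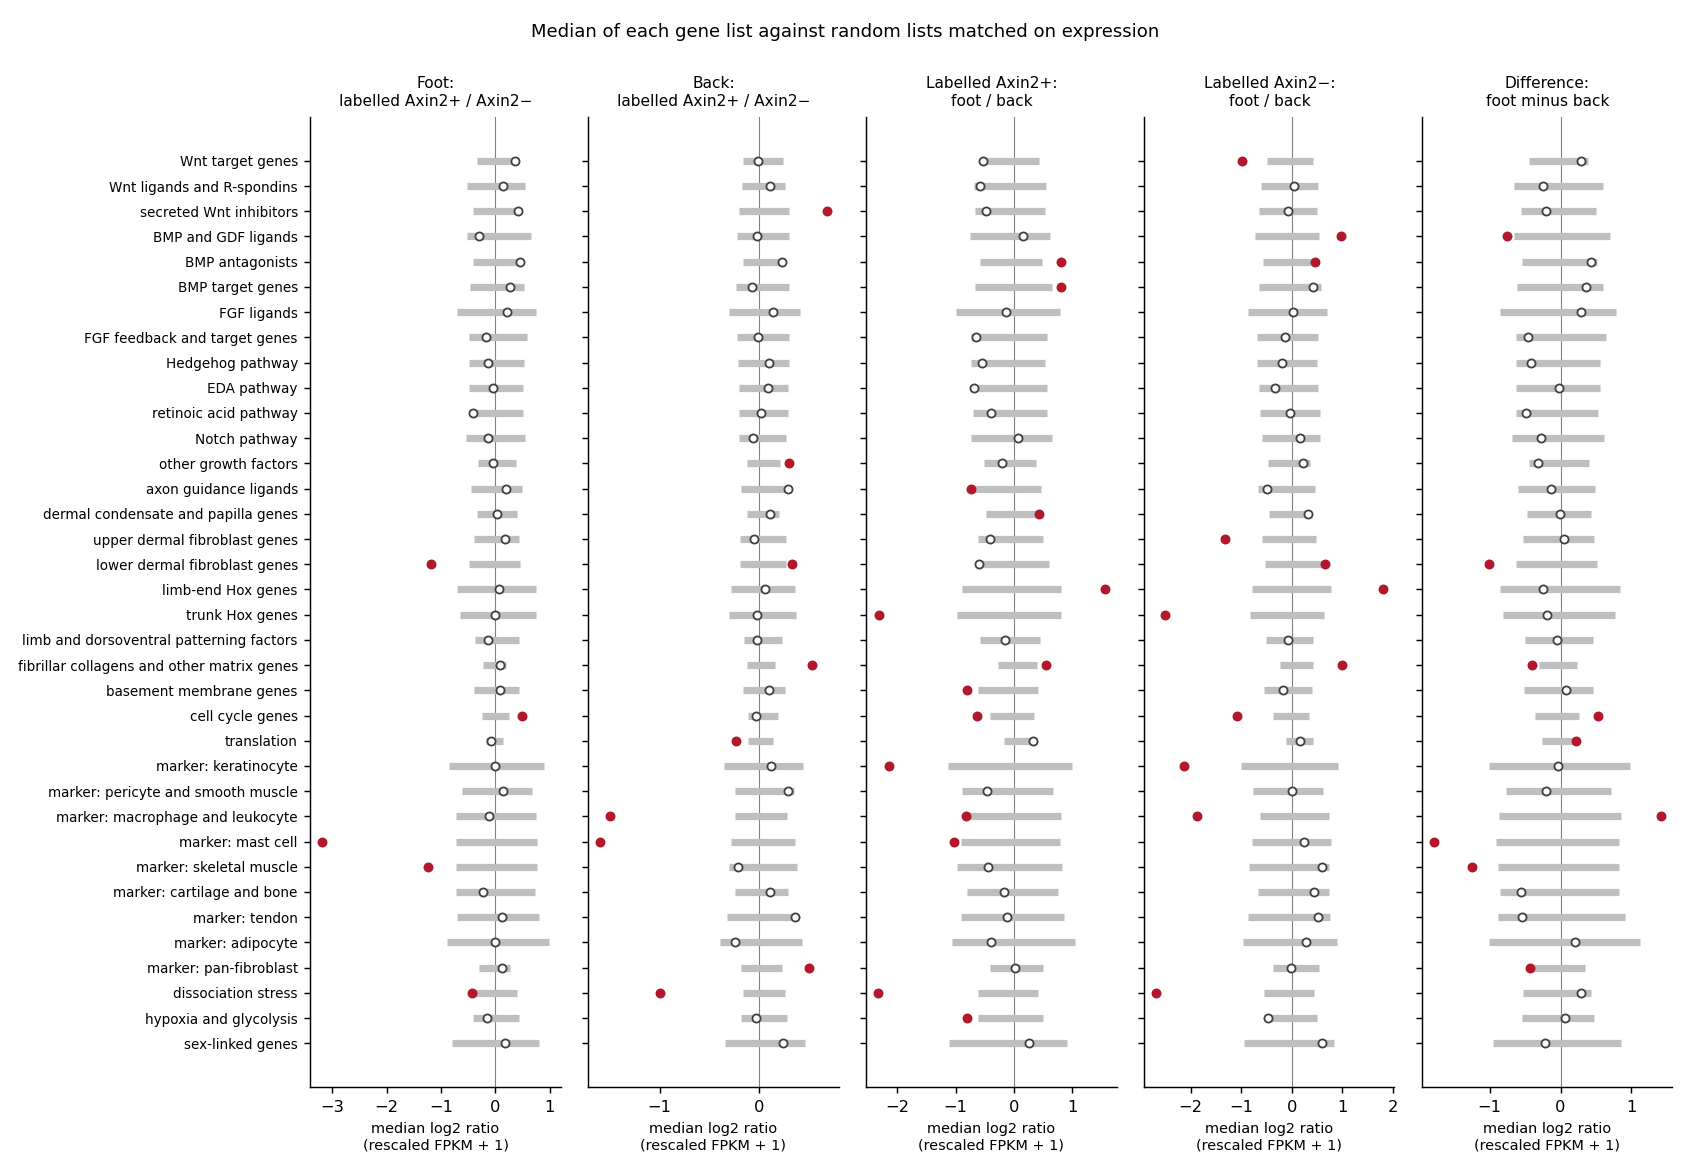
Median rescaled log2 ratio of 36 gene lists in 5 comparisons; grey bars span the central 95% of 10000 random lists and filled red points lie outside it. In the foot, lower dermal genes lie at -1.18 and cell cycle genes at 0.49; in the back, secreted Wnt inhibitors lie at 0.69.

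Of 180 list positions, 53 lay outside the central 95% as deposited and 49 after rescaling, where 9 would by chance for independent lists. Lists that share genes, and comparisons that share libraries, are not independent. The lists of Wnt ligands and R-spondins, FGF ligands, FGF feedback genes, Hedgehog, EDA, retinoic acid and Notch pathways, limb and dorsoventral factors, and pericyte, cartilage and bone, tendon, adipocyte and sex-linked markers had no position outside in either scaling. Other settings put some of them outside: FGF feedback genes in the back at percentile 99.99, in the difference at 0.13 and between the libraries labelled positive at 0.68 by the mean over members, and in the back at 99.6 with members of at least 5 FPKM. Spry2, 1 of these genes, raised the back mean, at 29.1 FPKM in the library labelled positive and listed at 0 in the other. Pericyte markers in the back lay at percentile 99.5 by the mean over members and 99.3 with members of at least 5 FPKM. Tendon markers in the back lay at 98.3 with a pseudocount of 0.1. By the mean, tendon markers between foot and back lay at 97.9 and 98.7 for the positive and the negative label, and sex-linked markers at 98.8 for the negative label. Single members of these lists still differed: Gli3 had a foot log2 ratio of -1.29 ± 0.67, Cyp26b1 was higher in the foot library labelled positive (1.17 ± 0.31), and Crabp1 was lower in the foot than the back for both labels (-2.13 ± 0.12 and -2.98 ± 0.08, with foot FPKM above their own bounds). Schwann markers (3 measured) had medians of -1.80 in the foot and 0.69 in the back, and melanocyte markers (4 measured) 0.21 and -0.08. Mitochondrial genes were joined into 1 locus and had no position.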

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

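The tests on exchanged foot labels, on counting error of Axin2, on the share of fibroblasts and on unstable estimates were chosen only after the result was seen; the test on depth was set before.

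Among well-measured genes, 16 had rescaled log2 ratios at least 2-fold one way in the foot and at least 2-fold the other way in the back, by the labels. With 1 library per group these differences were not tested. They rest on the labels of both skins. If those of the foot alone were exchanged, the 16 genes would move alike in both skins. The 13 and 9 well-measured genes that moved alike would then be the opposed ones. Below 0 (foot minus back) were Fbn1 (-3.69), Rnf141 (-3.42, half-width 2.77), Hnrnpl (-3.37), Efemp1 (-3.28), Mfap5 (-3.02), Clu (-2.70), Dcun1d5 (-2.59), Stx18 (-2.55), Anxa3 (-2.23), C87436 (-2.22) and Pdpn (-2.13). Above 0 were Myh9 (3.63), Lyrm1 (3.59), Rgs2 (3.51), 2310004N24Rik (2.79) and Nat10 (2.59). Fbn1 had log2 ratios of -2.45 in the foot and 1.24 in the back, and Mfap5 of -1.97 and 1.06. The list of lower dermal fibroblast genes, which holds Mfap5 but not Fbn1, had medians of -1.18 and 0.34 and a median difference of -1.01. Several of these genes fall outside the naming rule and were chosen after their values were seen.

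Unnamed assembled loci, not used in the comparisons, carried signal in every library. Loci with a lower bound of at least 5 FPKM numbered 6689 and 6323 in the foot libraries labelled positive and negative, and 1209 and 964 in the back libraries. Their nature was not analysed here, and no explanation was tested.

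Axin2 was not higher in the foot library labelled positive than in the one labelled negative. Counting error hiding an excess of 2-fold or more is argued against, since the upper end of the rescaled log2 ratio was 0.35. An exchange of the 2 foot labels stays open: the median of the 16 other Wnt targets was 0.39, at percentile 97.77 of random lists (central range -0.33 to 0.38) with 12 members above 0, a position on the edge of that range and on the side of the labels. Axin2 itself points neither way beyond its bounds, and the targets pass the range by too little to exclude an exchange, so the labels and an exchange cannot be told apart from these values. A real difference between LacZ protein and Axin2 transcript within foot mesenchyme was not tested, nor was an exchange of the 2 back labels.

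Mast cell markers were lower in both libraries labelled positive, and leukocyte markers in the back (median -1.50). In the foot leukocyte markers had a median of -0.12, inside the random range, and their difference between the skins lay outside (percentile 99.93) but not with a pseudocount of 0.1 (percentile 96.5). In the back, a smaller share of fibroblasts in the library labelled negative is argued against only in the form that raises all other cell types alike. Keratinocyte, endothelial and pericyte markers (13 genes, median 0.30, SD 0.668) lay 2.03 above blood-derived markers (13 genes, median -1.73, SD 0.690). This gap exceeded the sum of both SDs (1.36). Fibroblast genes were not part of the test. The marker types were pooled, and whether fibroblasts share some of the pericyte markers was not examined. The gap argues against that form only if they do not. Pan-fibroblast and matrix genes were lower in the library labelled negative, so a smaller share of fibroblasts as such stays open. In the foot the gap was 0.72 between 9 genes (median 0.01, SD 0.835) and 5 genes (median -0.71, SD 2.72), and with a sum of SDs of 3.56 it decides nothing. Blood cells entering the gate labelled negative, or a real difference between skins in resident mast cells and leukocytes, may account for the markers and were not tested.

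More genes were at least 2-fold apart in the foot sort than in the back sort. Estimates that fail the limits of the well-measured set are argued against as the only cause. Among well-measured genes 750 of 4465 (16.8%, exact Clopper-Pearson 95% interval 15.7 to 17.9) were apart in the foot. In the back 244 of 4598 (5.31%, 4.68 to 5.99) were apart, a ratio of 3.17. Genes are not replicates, and each skin has 1 pair of libraries. These intervals and those below therefore do not cover variation between libraries. The well-measured set still holds imprecise foot values, such as Chn2 at 8.73 FPKM (2.60 to 15.7) in the library labelled positive. Imprecise estimates are therefore not excluded. Lower depth of the foot libraries stays open as a candidate explanation: among the genes with the most expected fragments (the top 10%) the shares were 43 of 552 (7.79%, 5.70 to 10.4) and 28 of 523 (5.35%, 3.59 to 7.65), a ratio of 1.46, just under the limit of 1.5 set before, with overlapping intervals. Counting noise alone, simulated at the implied depths, put 0.378% of unchanged genes apart in the foot and 0% in the back. The simulation held no errors of read assignment and no failed estimates, so it cannot decide on depth as the whole explanation. A larger difference between the sorted fractions of the foot, by site or stage, stays open and was not tested.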

How the results depend on the processing

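The settings with protein-coding genes only, genes not listed at 0 and well-measured genes were chosen only after the result was seen; the others were planned. 1 list position reversed: BMP and GDF ligands in the foot minus back difference went from percentile 2.47 to 78.19 with the mean over members, and the cause was not tested. Counts below are genes higher plus lower, to be read beside 1950 in the foot, 626 in the back, 2625 and 3422 in foot against back (labelled positive, then negative), 2847 for the difference and 77 for the overlap; all changes beyond 1.5 times are listed. With a threshold of 1.5-fold they were 3585, 1509, 4600, 5432 and 4736 for the foot, the back, the 2 site comparisons and the difference, and with 4-fold 620, 207, 854, 927 and 964, which follows from the threshold. With an FPKM minimum of 1 the foot, the back, the site comparison labelled positive, the difference and the overlap had 3288, 1009, 4067, 4431 and 138; with no minimum the first 4 of these had 3288, 1009, 4067 and 4513. With a minimum of 20 the counts were 749, 260, 1105, 1815 and 1194, since fewer genes were tested. A pseudocount of 5 gave 1092, 369, 1597, 2238 and 1717, and 50 for the overlap, since it shrinks the ratios of low genes. Well-measured genes after rescaling gave 750, 244, 1295, 1245 and 998, and 22 for the overlap; these values are also rescaled, so the gene set and the scaling changed together and the cause was not tested. Scaling changed the site comparison labelled negative: median ratio gave 2184 (975 higher, 1209 lower), trimmed mean 2189 (996 and 1193) and quantile normalization 2220 (1104 and 1116), against 3000 and 422 as deposited; the shift of 0.75 that scaling removes shows the cause. Median-ratio scaling also turned which direction held more genes in the foot (688 higher and 1262 lower, then 841 and 753) and in the site comparison labelled positive (1707 and 918, then 1115 and 1332). Restricting lists to members of at least 5 FPKM put 35 of 120 positions outside, where 6 would be by chance.

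Of 180 list positions, 170 kept their place inside or outside with a pseudocount of 0.1, 174 with median-ratio scaling, 173 with quantile normalization and 156 with the mean over members; 108 of 120 did with members of at least 5 FPKM. Of 468 log2 ratios of named genes, 84 moved beyond their half-width with a pseudocount of 0.1, 242 with a pseudocount of 5, 204 with median-ratio scaling, 200 with the trimmed mean and 195 with quantile normalization. No replicate could be left out because each group holds 1 library. A paired analysis of the labels by skin across all 4 libraries would leave 1 residual degree of freedom and was not run, since the difference between the skins is itself compared. Depth limits the foot most: at about 2.70 M implied fragments in the library labelled positive, the median half-width of the bounds was 23.0%.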
